A study of Mus musculus with 18 samples.

How the data were processed

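Gene expression was measured in 18 one-colour microarray hybridisations (Agilent Whole Mouse Genome, 45018 features, 41174 gene probes) of Cy3-labelled RNA. The arrays fall into 6 groups of 3: mouse embryonic fibroblasts (MEFs), hepatocyte-like cells made from MEFs (iHep), budding organoids grown from induced intestinal stem cells (iISC) or from adult intestinal crypts, and mixed spherical and budding organoids grown from induced fetal intestinal progenitor cells (iFIPC) or from fetal intestine (FI). The authors ran Feature Extraction on the scans, and the deposited file of each array gives the processed signal as an intensity on the linear scale, background-subtracted and detrended, with no scaling between arrays. Raw spot means and local background medians are deposited as intensity values too. The deposited flags (well above background, saturated, non-uniform, population outlier) are 0 or 1 and belong to the other kind of column. The authors' series matrix holds the processed signal quantile normalised over the arrays on the linear scale: every column had a median of 59.32, and its correlation with a quantile normalization computed here from the array files was 1. It served as an alternative only. The submitters' notes give Feature Extraction 9.5.1.1 for all arrays, while per the file headers this holds for the MEF and iHep arrays alone and the organoid arrays were extracted with 10.7.1.1 on another scanner model and protocol. The MEF and iHep arrays are marked as re-analysed by the submitters, and the codes in the iHep titles differ between the 3 arrays and are not explained, so that these may be different conversions treated here as replicates.

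Spots with an outlier flag were left out (62 to 107 per array), and the remaining spots of a probe were averaged (245 probes had 10 spots). At most 4 probes of an array were saturated, and 65 probes lacked a value on some array and were not used. Signals were taken to log2, and the 75th percentile of the gene probes of each array was subtracted. Levels are therefore log2 units above or below the 75th percentile of the array. Probes were named from the deposited annotation and a table of RefSeq names, by RefSeq accession (24844 probes), symbol (6045) or synonym (1810), and 8475 probes had no name. Of 19713 named genes, 8605 had several probes, and the probe with the highest mean level in each fit stood for the gene. No genome sequence was at hand. Positions are those of the probes on mm9, as printed in the organoid files, with identifiers as gene symbols.

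MEF arrays 2 and 3 were nearly identical: the spread of their log2 differences over 27186 probes was 0.073, against 0.0899 expected from the noise of single spots in 10-spot probes, while the other 17 within-group pairs had spreads of 0.197 to 0.536. They share a slide, and the means of 189 such probes still differed more than spot noise alone would give on a chi-square scale (9.57 per probe, against at least 119 in the other pairs). They were averaged and counted as 1 sample, which leaves 17 samples and an n of 2 for the MEFs. This step was chosen after the data and the counts over 18 arrays had been seen, and the fit with 18 separate arrays, as first designed, was run as an alternative.

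Groups were compared with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8, and statmod 1.5.0): lmFit with 1 mean per group, contrasts and moderated tests with default settings, two-sided. The 4 comparisons with MEFs or iHep cells came from a fit over all 17 samples, and the 5 among the organoids from a fit over their 12 samples. A gene was tested when its probe was well above background on every array of at least 1 of the groups compared. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1. Errors printed with log2 changes are standard errors from that fit. Where only some arrays of the dimmer group were well above background, the fitted change is printed, and its size and error rest partly on levels at background. Where a gene was well above background on no array of the dimmer group, the change is printed as a lower bound, "at least N-fold": the bright group's mean level minus that of the dim group, with each dim array set to no less than its lowest level among probes well above background. Array signals carry no counts, so the number of arrays limits the precision, and 3 samples against 3 cannot give an exact permutation p under 0.1.

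Before the data were examined, the comparisons, the test, 31 gene lists, 23 anchor genes, the alternatives and the rule for naming genes were fixed. The rule names the anchors where a comparison is about them, up to 4 called members of a list (those with the largest change, and members against the list's direction), and the 5 largest rises and 5 largest falls whose samples do not overlap and that are well above background throughout the higher group. Symbols of clones and predicted genes were left out, and a few of the genes the rule names are not reported here. The lists cover the factors used in published conversions (named in the text as reprogramming factors), epithelium, intestinal transcription factors, intestinal stem cell and Wnt target genes, Paneth, goblet, enteroendocrine and tuft cells, and absorptive enterocytes. Others cover suckling-type and weaned-type enterocytes, ileal bile acid handling, fetal intestinal spheroids, fetal and imprinted growth genes, stomach, proximal small intestine, colon and hindgut, and hepatocytes. Further lists are the Hox clusters, pluripotency, cell cycle, cholesterol synthesis, interferon response, antigen presentation, YAP targets, and glutathione and xenobiotic metabolism. The last cover other cell types a culture could hold: fibroblasts and mesenchyme, smooth muscle and myofibroblasts, immune and blood cells, endothelium, and enteric neurons and glia. Each list was tested with camera at a preset correlation of 0.01 on at least 3 members, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Counts of called members are given over all genes tested and adjusted over the list alone.

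The arrays lie on 5 slides. Slide 1 holds MEF 1 and the iHep samples, slide 2 MEF 2 and 3, slide 3 the iISC samples and iFIPC 2, slide 4 crypt 1 and the FI samples, and slide 5 crypt 2 and 3 with iFIPC 1 and 3. Each organoid comparison and the one between iHep cells and MEFs was refitted with slide as a term and, where a slide holds both groups, within that slide. No slide holds both iISC and crypt samples or both iFIPC and FI samples, so these rest on the term alone. Log2 changes given with the term are fitted values and are no bounds where a group lay at background. Other alternatives were quantile normalization, the series matrix values, normexp background correction with an offset of 50, means over the probes of a gene, no filter and a stricter one (well above background in all groups compared), no fold threshold, trended and robust moderation, a random slide effect, the groups of a comparison alone, all groups in 1 fit, and each sample left out in turn. The procedure was tested on simulated data with 200 changed genes: at a log2 change of 1, 37.3 to 65.7% of the changed genes were recovered, at 2, 67.2 to 92.5%, and at 3, 80.3 to 97%. Between 2.6 and 6.3% of genes called by adjusted p alone were false, and a shifted list was found in all 9 comparisons with no other list called. The simulated noise was independent between genes and held no slide effect. These results therefore do not cover correlated genes within a list or differences between slides. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.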

Results

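The series was made to follow the conversion of mouse fibroblasts into intestinal progenitors, and it sets organoids grown from converted cells beside organoids grown from intestine. RNA from 6 kinds of culture was measured on microarrays, 3 arrays each. There were MEFs (fibroblasts, not labelled as the ones converted) and iHep cells (hepatocyte-like cells made from MEFs). Budding organoids came from induced intestinal stem cells (iISC organoids) or from adult crypts (crypt organoids). Spherical and budding organoids came from induced fetal intestinal progenitors (iFIPC organoids) or from fetal intestine (FI organoids). MEF arrays 2 and 3 were nearly identical (spread of 0.073 log2), although their repeated probes differed by more than spot noise alone would give, and were averaged to 1 sample after the data had been seen. The 75th percentile of the signal lay between 714.1 and 1484.4 intensity units, and 56.14 to 68.65% of probes were well above background. Nothing in the labels says that samples came from separate animals or cultures, so every p-value measures only the spread between these samples.

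Each of the 17 samples was closest to a sample of its own group. Over 15548 genes, mean Pearson correlations within groups ran from 0.9669 (iHep) to 0.9857 (crypt). These are correlations across genes, which are not independent replicates. iISC organoids were closer to crypt organoids (0.9671) than to FI (0.9618) or iFIPC organoids (0.9484). iFIPC organoids were closer to iISC (0.9484) than to FI organoids (0.942). Over single pairs of samples these ranges overlapped (0.9414 to 0.9597 and 0.9364 to 0.9474). So did those of iISC with crypt and with FI organoids (0.962 to 0.9707 and 0.9558 to 0.9682). iFIPC 2 shares a slide with the iISC samples and no FI sample shares one with iFIPC samples, so slide may enter the order. MEFs lay far from every organoid group (0.612 to 0.6841), and iHep cells lay nearer to MEFs (0.84) than to iFIPC (0.8216) or iISC organoids (0.7718). The MEF and iHep arrays were scanned and extracted separately from the organoid arrays, and 8 spike-in controls were brighter in them by 0.28 to 1.2 log2 (median 0.9), so that in any comparison across these sets array set goes with cell type, and changes of about that size cannot be told apart from a set effect.

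**Figure D1:**
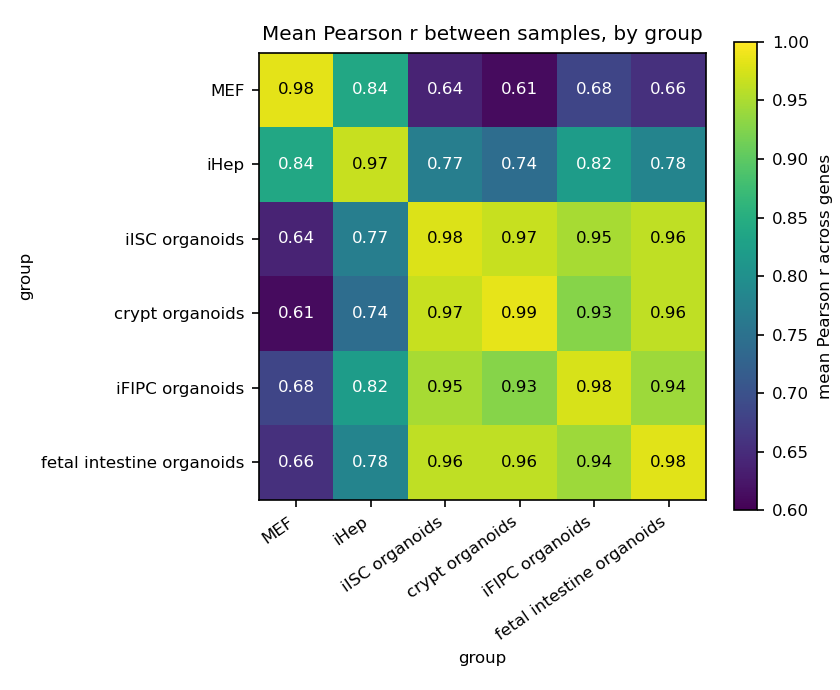
Mean Pearson correlation (across genes, log2 levels) between the samples of each pair of the 6 groups. The 4 organoid groups form a block between 0.9268 and 0.9857, with MEFs and iHep cells apart from it.

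**Figure D2:**
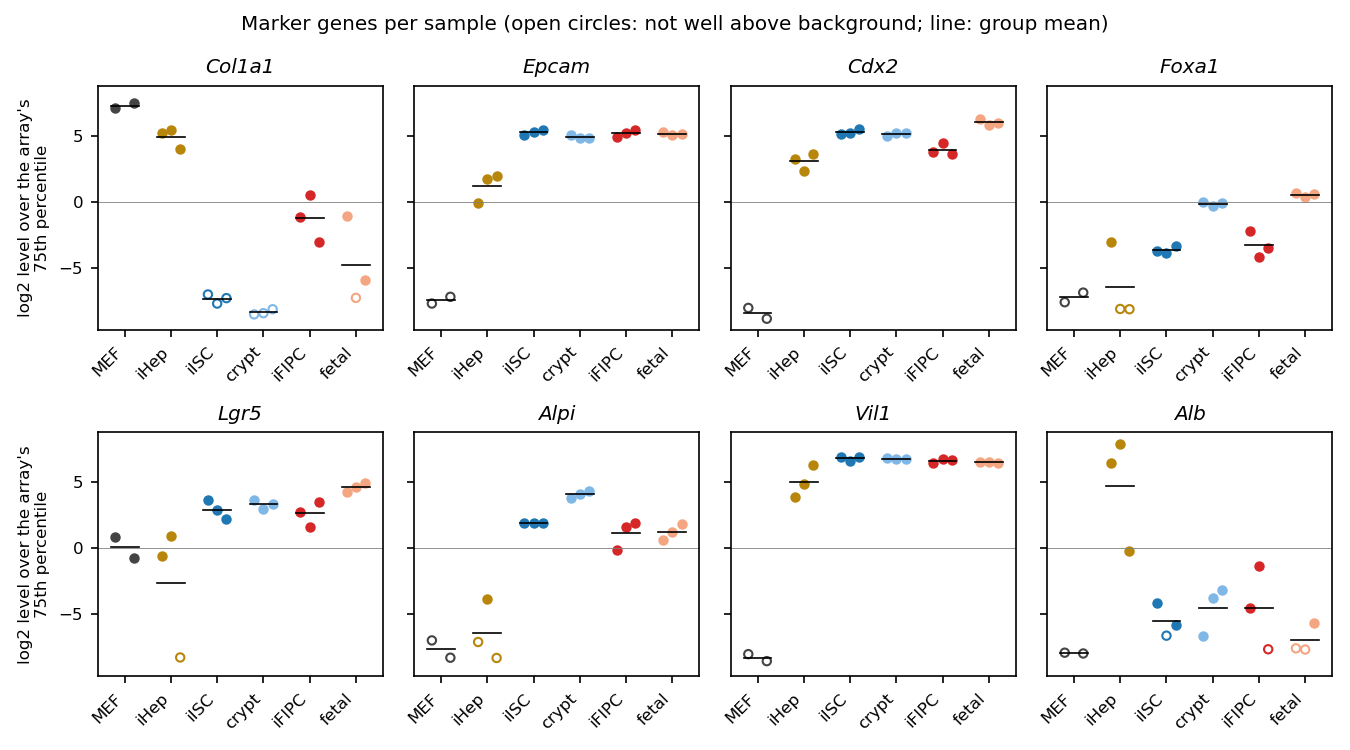
Level of 8 anchor genes in each sample, in log2 units relative to the 75th percentile of its array, with open points for probes not well above background and a line at the group mean. Col1a1 was high in MEFs, and Epcam, Vil1 and Cdx2 in all 4 organoid groups.

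iHep cells against MEFs set a conversion to another endodermal cell type beside MEFs, though no label says that these MEFs were the ones converted. iHep cells had gained a broad epithelial programme and intestinal as well as liver genes. Cdh1, the epithelial cadherin, was at least 2080-fold higher (adjusted p = 1.09e-13), the intestinal homeobox gene Cdx2 at least 615-fold (1.09e-10) and the brush border gene Vil1 at least 2360-fold higher. The largest rises were those of the goblet cell peptide Tff3 (at least 17500-fold), the plasma protein genes Ahsg (at least 12900-fold) and Fgb (at least 13900-fold), Spink1 (at least 20200-fold) and the stomach gene Gkn2 (at least 7180-fold). The largest falls were those of the matrix genes Mfap4 (log2 change -11.05 ± 0.44), Aspn (-9.18) and C1qtnf3 (at least 201-fold lower), of Fxyd6 (-9.09) and of Vat1l (at least 121-fold lower). Albumin differed between the iHep samples, with levels of 6.46, 7.92 and -0.20, and was at least 1970-fold above the MEFs on average. The iHep titles carry 3 unexplained codes, so that these samples may be different conversions and their mean and spread may mix them.

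Among the lists, 24 of 25 epithelial genes rose and none fell (24 adjusted over the list alone; camera adjusted p = 3.19e-25). So did 11 of 16 intestinal transcription factors (1.09e-06), 3 of 3 tested reprogramming factors (0.000576) and 22 of 28 genes of glutathione and xenobiotic metabolism, where 1 fell (2.5e-11). The reprogramming factors tested were Hnf4a, Gata6 and Cdx2. Foxa3 was well above background in no iHep sample, and Foxa1 and Foxa2 in 1 of 3 each, so these were not tested. All reprogramming factors are also members of the intestinal transcription factor list, so these lists are not independent, here and below. The labels do not say which factors were introduced for the conversions, so a rise of this list may be part of the treatment. Gsta2 rose by 12.19 on the log2 scale. Hepatocyte genes rose for 14 of 24 (15 adjusted over the list alone; adjusted p = 2.62e-05, and adjusted p = 0.0636 with an estimated correlation). Interferon response genes rose for 15 of 29 (3.03e-06; adjusted p = 0.288 with an estimated correlation), among them the antiviral genes Oas2 (9.09 ± 0.71) and Mx1 (at least 42.8-fold). Cholesterol synthesis genes fell for 18 of 24 (19 adjusted over the list alone; 7.35e-05; adjusted p = 0.438 with an estimated correlation), with Cyp51 at -2.65. All 11 smooth muscle genes fell (1.09e-06), and so did 9 of 13 immune and blood cell genes with 1 rise (0.000486). Fibroblast genes fell for 20 of 30 (21 adjusted over the list alone; 4.85e-05; adjusted p = 0.288 with an estimated correlation). Antigen presentation genes rose for 9 of 15 and fell for 2 (0.00208; adjusted p = 0.185 with an estimated correlation). The type I collagen gene Col1a1 was not called (-2.38 ± 1.38, adjusted p = 0.179). Its error is pooled over all 6 groups and includes the wide spread among FI organoids (standard deviation 3.25). Its levels did not overlap, at 7.10 and 7.44 in MEFs and 5.21, 5.45 and 4.02 in iHep cells. The colon and hindgut list (3 rose and 4 fell of 12, camera adjusted p = 0.512), the pluripotency list (2 and 2 of 9, 0.848) and the cell cycle list (2 and 0 of 35, 0.645) were not called, and their median, mean and test differed in sign.

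In limma, 3988 of 14400 genes were called between iHep cells and MEFs, 1712 higher and 2276 lower (42.9% higher; median change of all genes -0.10). Samples did not overlap for 62.5% of genes tested, where chance gives 20% with 3 against 2. A fit with slide as a term called 1641 genes (1564 of them shared), and the fit within slide 1, where MEFs have 1 sample, 1782 (1615 shared). All 17 lists called here were called the same way with the term, and 6 were called with an estimated correlation: reprogramming factors (0.0397), epithelium (0.00206), intestinal transcription factors (0.00503), smooth muscle (0.0432), xenobiotic metabolism (0.0432) and immune and blood cells (0.0397).

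Organoids from induced progenitors were compared with MEFs to see how far the fibroblast programme had been replaced. Fibroblast genes were lower in both, and genes of several intestinal cell types were higher. In iFIPC organoids, all 30 fibroblast genes fell and in iISC organoids all 30 fell too, while all 27 epithelial genes rose in each. The fibroblast list had a camera adjusted p = 1.12e-11 and 1.41e-12 (adjusted p = 0.0645 and 0.0554 with an estimated correlation). Col1a1 fell by 8.51 ± 1.38 in iFIPC organoids and at least 10700-fold in iISC organoids (adjusted p = 0.000136 and 8.67e-07). Cdx2 (probe on chromosome 5, 148112547 to 148112606) was at least 1130-fold higher in iFIPC organoids (adjusted p = 2.18e-11) and at least 2860-fold higher in iISC organoids (8.96e-12), and the endodermal regulator Hnf4a at least 584-fold and 952-fold. The R-spondin receptor gene Lgr5, a stem cell marker, was above background in MEFs as well and was not called (2.58 ± 1.87, adjusted p = 0.241 for iFIPC, and 2.86 ± 1.87, 0.188 for iISC). These errors are pooled over all groups and are widened by the iHep samples (standard deviation 4.95), so the missing calls do not show equal levels. The tuft cell gene Dclk1 was lower in iFIPC organoids (-2.36 ± 0.39) and not called in iISC organoids (-0.65 ± 0.39).

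Largest among the rises in iFIPC organoids were the Paneth cell defensin Defa23 (at least 10200-fold), Lypd8 (at least 8910-fold), the antimicrobial lectin Reg3b (at least 7670-fold), Vil1 (at least 7200-fold) and Tspan1 (at least 6650-fold). In iISC organoids they were Defa23 (at least 12000-fold), the brush border disaccharidase Sis (at least 18700-fold), Reg3b (at least 9670-fold) and Vil1 (at least 8320-fold). The largest falls were of matrix and contractile genes: Ogn (at least 2250-fold), Lox (at least 2680-fold), Loxl1 (at least 2720-fold) and Cnn1 (-11.93) beside the growth factor Ptn (at least 3250-fold) in iFIPC organoids. In iISC organoids they were of Col1a1, Mgp (at least 8220-fold), Col5a1 (at least 4780-fold), Serpinf1 (at least 4670-fold) and the surface marker Thy1 (at least 5390-fold).

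By list, for iFIPC and then iISC organoids, the genes that rose were 18 and 18 of 19 Paneth cell genes (camera adjusted p = 7.28e-12 and 2.17e-10), 22 of 24 and 21 of 23 intestinal transcription factors (1.79e-09 and 9.54e-09) and 6 and 6 of 6 reprogramming factors (0.000503 and 0.000654). Rises were also called for 40 of 44 and 44 of 45 absorptive enterocyte genes (8.96e-15 and 1.23e-15). The same held for 19 of 23 and 18 of 22 goblet cell genes (2.15e-08 and 3.75e-07), and 23 of 29 and 26 of 30 enteroendocrine genes, with 2 falls in each (7.15e-07 and 1.11e-07). Adjusted over the list alone these counts were the same except for 41 enterocyte genes in iFIPC and 27 enteroendocrine genes in iISC organoids. Weaned-type enterocyte genes rose for 11 of 12 in each (1.88e-06 and 1.27e-05) and ileal bile acid genes for 5 of 6 in each (0.0091 and 0.02). Stem cell and Wnt target genes rose for 14 and 13 of 26, with 2 falls in each (0.00145 and 0.00555; adjusted p = 0.242 and 0.312 with an estimated correlation). Tuft cell genes rose for 5 of 18 and 10 of 20, with 1 fall in each, called as a list in iISC organoids only (0.249 and 0.0167; adjusted p = 0.286 in iISC organoids with an estimated correlation). Cell cycle genes rose for 15 and 16 of 35, with 1 fall in each (0.000471 and 0.00161; adjusted p = 0.465 and 0.525 with an estimated correlation). Falling lists were fetal and imprinted growth (15 of 19 in each; 7.29e-05 and 0.000171) and YAP targets (11 and 13 of 18; 0.00178 and 0.000135). Immune and blood cell genes (8 of 13 fell in each; 0.0099 and 0.00406), endothelium (7 of 11 and 7 of 10; 0.0211 and 0.018) and enteric neurons and glia (7 of 11 in each; 0.0286 and 0.0174) fell too. Tested with an estimated correlation, adjusted p = 0.0645 and 0.0622 for enterocytes, 0.0645 and 0.0761 for goblet cells, and 0.0961 and 0.0761 for enteroendocrine cells. It was 0.0577 and 0.0575 for weaned-type genes, 0.102 and 0.161 for ileal bile acids, and 0.0645 and 0.0521 for YAP targets, each again with an estimated correlation. For immune cells, adjusted p = 0.0645 and 0.0534 with an estimated correlation. It was 0.0645 and 0.073 for endothelium, 0.0685 and 0.0575 for neurons, and 0.0521 for imprinted growth in iISC organoids. Suckling-type enterocyte genes went both ways (6 rose and 6 fell of 14 in iFIPC organoids, adjusted p = 0.771). In iISC organoids this list, the stomach list (5 rose and 2 fell of 14; 0.809) and the antigen presentation list had medians, means and tests of differing sign without a call.

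limma called 6500 of 14933 genes for iFIPC organoids (3018 higher, 46.4%) and 7164 of 14784 for iISC organoids (3406 higher, 47.5%), and samples did not overlap for 79.2% and 80.7% of genes, where chance gives 20%. Under an estimated correlation, epithelium, intestinal transcription factors, Paneth cell and reprogramming factor lists stayed called in each (adjusted p = 0.000737 to 0.0229 in iFIPC organoids and 0.00113 to 0.0311 in iISC organoids), and smooth muscle, fetal and imprinted growth and xenobiotic metabolism (0.0498 each) in iFIPC organoids alone. The fibroblast list was not (adjusted p = 0.0645 and 0.0554 with an estimated correlation). No slide holds MEFs and organoids together.

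iFIPC organoids against iHep cells ask what sets intestinal apart from hepatocyte-like conversion. Genes of differentiated intestinal cells were higher in the organoids, and the plasma protein genes Ahsg, Fgb and Hp were lower. Paneth cell genes rose for 18 of 19 (camera adjusted p = 5.19e-12, and adjusted p = 0.032 with an estimated correlation), led by Defa23 (at least 9070-fold, adjusted p = 2.24e-14), Defa21 (at least 3100-fold) and Itln1 (at least 5930-fold). Enteroendocrine genes rose for 25 of 29 (1.9e-10; adjusted p = 0.0786 with an estimated correlation), with the granule protein Chgb at least 6640-fold higher. Enterocyte genes rose for 38 of 44 (39 adjusted over the list alone; 5.19e-12; adjusted p = 0.133 with an estimated correlation), and stem cell and Wnt target genes for 20 of 26 (9.4e-06; adjusted p = 0.191 with an estimated correlation), with Lgr5 at 5.27 ± 1.67 (adjusted p = 0.0157). Lgr5 levels were -0.58, 0.95 and -8.28 in iHep 1, 2 and 3, the last not well above background, so that much of this change rests on iHep 3. Intestinal transcription factors rose for 17 of 24 and fell for 2 (2.01e-05; adjusted p = 0.0124 with an estimated correlation), with Cdx1 at least 79.9-fold higher. Cdx2 (0.87 ± 0.32, adjusted p = 0.0301), Gata6 (0.06, 0.859) and Cdh1 (0.54, 0.0135) were not called.

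On the other side, Ahsg was at least 16300-fold lower in iFIPC organoids, Fgb changed by -13.38 ± 1.36, Hp by -11.97 and Apoa1 by -5.19. The hepatocyte list was split (6 rose and 13 fell of 30, adjusted p = 0.115): the urea cycle genes Otc (8.94) and Cps1 (7.59), also expressed in small intestine, rose. Fibroblast genes fell for 27 of 29 (1.9e-10; adjusted p = 0.0979 with an estimated correlation). Interferon genes fell for 27 of 29 (8.18e-07; adjusted p = 0.252 with an estimated correlation), with Oas2 at -8.71. Cholesterol synthesis genes rose for 18 of 24 (1.52e-06; adjusted p = 0.295 with an estimated correlation). The fetal spheroid list (median -0.54, mean 0.098, camera adjusted p = 0.757) and the immune list (-0.18, 0.965 and 0.998) were uncalled, with median and mean of opposite sign. In all, limma called 4884 of 14366 genes, 2503 higher and 2381 lower (51.2% higher), and samples did not overlap for 64.4% of genes, where chance gives 10%. Array set goes with cell type here too.

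iISC organoids against crypt organoids ask how close the induced adult type came to its native counterpart. Most intestinal genes did not differ detectably, while part of the Hox genes, the single genes Tbx15 and Pitx1, and some fetal genes did. The Hox list as a whole was not called with an estimated correlation. Hoxa11 (chromosome 6, 52192107 to 52192166) was at least 453-fold higher in iISC organoids (adjusted p = 3.7e-05), Hoxa10 8.44 ± 0.96 log2 higher (0.00203), and the limb and trunk mesoderm regulator Tbx15 (chromosome 3, 99157901 to 99157960) at least 259-fold higher (3.97e-06). Pitx1, a hindlimb homeobox gene, changed by -9.59 ± 0.93 (0.00117). Hoxa10 was well above background in 1 of 3 crypt samples and Pitx1 in 1 of 3 iISC samples, so these sizes rest partly on background levels. The acute-phase gene Saa2 (8.57 ± 1.69) and the butyrate transporter gene Slc5a8 (8.04 ± 1.65) also rose, and Gimap5 (at least 67-fold), Slc1a3 (at least 27.7-fold) and Prss12 (-6.17) fell. The probes of Slc1a3 disagreed, with fitted changes from -6.925 to 0.093. Those of Gata6, which was not called here, ran from -0.983 to 1.683, and changes of Gata6 in other comparisons rest on its brightest probe.

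**Figure D3:**
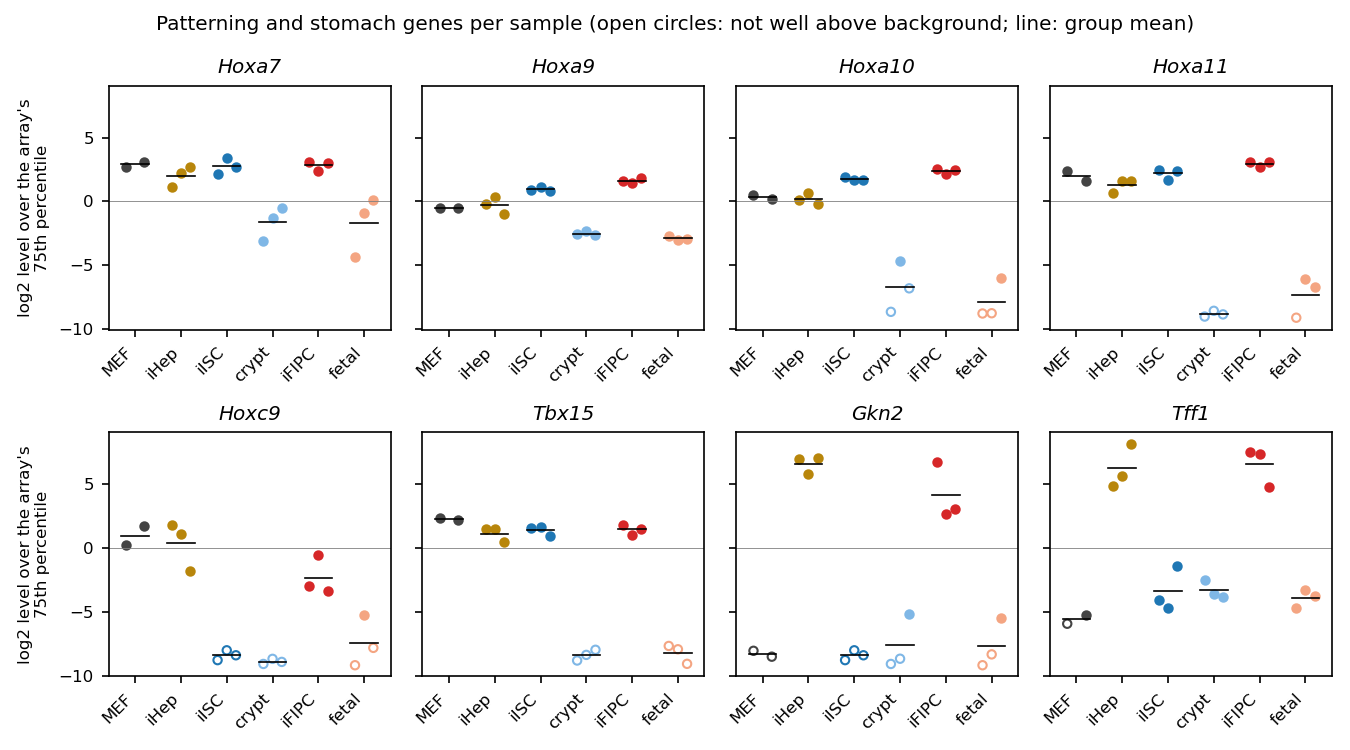
Level of 8 genes of body position and stomach in each sample, in log2 units relative to the 75th percentile of its array, with open points for probes not well above background and a line at the group mean. Hoxa10, Hoxa11 and Tbx15 were well above background in MEFs, iHep cells and both induced organoid groups, and low in both native ones. Gkn2 and Tff1 were high in iFIPC organoids and iHep cells.

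Hox genes rose for 7 of 16 (7 adjusted over the list alone; camera adjusted p = 2.52e-08, and adjusted p = 0.0564 with an estimated correlation), including Hoxd9 (at least 6.24-fold) and Hoxa13 (at least 5.59-fold). Fetal spheroid genes rose for 6 of 24 (9 adjusted over the list alone; 2.52e-08; adjusted p = 0.343 with an estimated correlation), led by Anxa8 (5.28), the growth factor gene Ereg (at least 8.86-fold) and Anxa1 (3.58). Among ileal bile acid genes the transporter gene Slc10a2 rose (6.46 ± 1.24). Secretory lists shifted upwards with few members called: enteroendocrine 4 of 30 (4 adjusted over the list alone; 0.000514), such as the hormone genes Pyy (5.26) and Nts (3.08). For tuft cells it was 1 of 19 (4 adjusted over the list alone; 9.95e-06), Rgs13 (1.88), and for goblet cell 1 of 22 (3 adjusted over the list alone; 0.000167). Under an estimated correlation these had adjusted p = 0.697, 0.343 and 0.573. Lower lists were proximal small intestine (2 of 13 fell, 5 adjusted over the list alone; 0.00027), with Onecut2 at -5.26 and Onecut1 at -5.22 (its other probe at -0.088), and xenobiotic metabolism (5 of 34, 10 adjusted over the list alone; 0.000342), with Ephx2 at -2.16. Also lower were immune and blood cells (2 of 10, 3 adjusted over the list alone; 0.0294), with Lcp1 at -3.40, and enterocytes (3 of 45; 0.0294), with the alkaline phosphatase gene Alpi at -2.21 ± 0.48. Their adjusted p = 0.343, 0.697, 0.343 and 0.86 with an estimated correlation, in that order. Cell cycle genes moved down as a list (3.35e-05; adjusted p = 0.697 with an estimated correlation) with none of 35 called. Of 26 stem cell genes Notum alone was called (2.44), and none of 27 epithelial and 19 Paneth cell genes were (2 Paneth cell genes rose adjusted over the list alone). Lgr5 (-0.42 ± 0.48, adjusted p = 0.649), Cdx2 (0.14 ± 0.22, 0.745), Hnf4a (0.07, 0.885) and Lyz1 (0.23, 0.811) were not called, which does not show that their levels were equal. Foxa1 changed by -3.53 ± 0.39 (0.0018). For the Paneth cell, reprogramming factor, fibroblast, pluripotency and neuron lists, median, mean and test differed in sign, with no list call.

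limma called 441 of 13605 genes, 267 higher and 174 lower (60.5% higher), and 25.6% of genes had no overlap between samples, where chance gives 10%. The count was 151 without crypt 2, 154 without crypt 3 and 267 without iISC 3. Fitting slide as a term left 28 genes called (20 shared), 42.9% of them higher. Of the 49 called genes named by rule, 6 stayed called, among them Hoxa11 (11.27 ± 1.30, adjusted p = 0.0218) and Tbx15 (10.22 ± 0.69, 0.00392), fitted values that are no bounds, as the crypt samples lay at background. Hoxa10 kept its size (7.85 ± 1.51) with an adjusted p = 0.0935. Of the 11 lists called, 9 were called the same way with the term, but not cell cycle (0.372) and YAP targets (0.0175 before and 0.147 with the term; adjusted p = 0.343 with an estimated correlation).

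iFIPC organoids against FI organoids ask the same of the fetal type. The induced organoids carried stomach, Hox and some fibroblast genes at levels far above those of FI organoids, and had lower levels of several intestinal regulators. The stomach genes Gkn2 (chromosome 6, 87329285 to 87329344; 11.80 ± 1.38, adjusted p = 9e-04) and Tff1 (chromosome 17, 31298471 to 31298530; 10.45 ± 0.94, 0.000206) rose most, followed by Hoxa11 (10.26 ± 0.63, 2.54e-05), Hoxa10 (10.25 ± 0.96) and Tbx15 (at least 338-fold). Gkn2 and Hoxa10 were well above background in 1 of 3 FI samples each, so their sizes rest partly on background levels. Sdr16c5 was at least 27.2-fold lower, the hormone gene Sst changed by -6.25 ± 1.07, Prr5l by -6.18 and the suckling-stage protease gene Cym was at least 29-fold lower. Cdx2 (-2.08 ± 0.22, adjusted p = 0.00052), Gata6 (-2.01 ± 0.23, 0.000865), Gata4 (-3.38), Foxa1 (-3.84 ± 0.39, 0.000487) and Lgr5 (-1.97 ± 0.48, 0.0168) were lower.

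Stomach genes rose for 7 of 18 and fell for 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00241, and adjusted p = 0.384 with an estimated correlation), with the mucin gene Muc1 at least 19.6-fold higher, Ctse at 5.11, and the acid pump gene Atp4a against the list at -2.17. Hox genes rose for 9 of 26 (1.45e-05; adjusted p = 0.0997 with an estimated correlation). Fetal spheroid genes rose for 13 of 29 (15 adjusted over the list alone; 4.93e-09; adjusted p = 0.351 with an estimated correlation), with Gja1 (5.53 ± 0.88), Spp1 (7.49) and Basp1 (at least 23.9-fold). Fibroblast genes rose for 8 of 16 (10 adjusted over the list alone; 6.35e-06; adjusted p = 0.0997 with an estimated correlation), with S100a4 (6.79 ± 0.55, adjusted p = 0.00012), Fn1 (6.11), Twist1 (at least 19.9-fold) and Dcn (at least 24.3-fold). Col1a1 varied within both groups (3.53 ± 1.38, adjusted p = 0.084): its levels were -1.17, 0.49 and -3.05 in iFIPC 1, 2 and 3, and -1.10, -7.29 and -5.92 in FI 1, 2 and 3. Cholesterol synthesis genes rose for 6 of 24 (8.32e-05; adjusted p = 0.57 with an estimated correlation), a direction that turned with slide as a term, and interferon genes for 6 of 27 with 1 fall (0.00303; adjusted p = 0.57 with an estimated correlation). So did goblet cell genes for 4 of 23 (0.00148; adjusted p = 0.406 with an estimated correlation), including Zg16 (4.83) and Clca1 (4.77), and YAP targets for 5 of 17 (0.027; adjusted p = 0.384 with an estimated correlation).

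Enteroendocrine genes fell for 14 of 30 (15 adjusted over the list alone; 0.000188; adjusted p = 0.406 with an estimated correlation), with the hormone genes Gcg (-3.79), Gip (-2.99) and Tac1 (-2.23) beside Sst, but with slide as a term the list turned upwards (adjusted p = 0.977) and none of these 4 stayed called. Intestinal transcription factors fell for 7 of 24 and rose for 2 (0.0403; adjusted p = 0.377 with an estimated correlation), among the rises Isx (5.81 ± 0.77), which limits vitamin A uptake. Reprogramming factors fell for 3 of 6 (0.00303; adjusted p = 0.0997 with an estimated correlation). Enterocyte genes went both ways (4 rose and 7 fell of 45; adjusted p = 0.792), with Fabp1 (-5.42) and Dpp4 (-5.14) lower and Mep1b (1.82) higher. Of 34 xenobiotic genes 3 rose (0 adjusted over the list alone; adjusted p = 0.141). Fetal and imprinted growth genes fell for 7 of 17 and rose for 1 (0.09), with Bex1 at -3.53, Peg3 at -2.87 and, against these, Mest at least 3.48-fold higher. Suckling-type genes fell for 3 of 13 and colon genes rose for 3 of 12 and fell for 1 (0.0545). Cell cycle genes moved down as a list with none of 35 called (0.00119; adjusted p = 0.602 with an estimated correlation), and epithelial genes up with 1 of 27 called (0.00661; adjusted p = 0.406 with an estimated correlation). For antigen presentation, median and test differed in sign (adjusted p = 0.884).

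The limma count was 1530 of 14378 genes, 810 higher and 720 lower (52.9% higher), with no overlap for 47% of genes (10% by chance), and 954 without FI 2. In the fit with slide as a term 113 genes were called (91 shared). Of 96 named called genes 13 stayed called, among them, as fitted values, Tff1 (11.26 ± 1.80, adjusted p = 0.0416), Cdx2 (-2.59 ± 0.29, 0.0107), Hoxa11 (10.07 ± 1.30, 0.0209), Tbx15 (9.25 ± 0.69, 0.00348) and S100a4 (8.28 ± 0.86, 0.0103). Gkn2 (10.39 ± 2.53, 0.114) and Lgr5 (-0.95 ± 0.70, 0.536) did not. Of 13 lists called, 10 were called the same way with the term. The enteroendocrine list was not (0.977), nor were cholesterol synthesis (0.219), both with the direction turned, and intestinal transcription factors (0.095).

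Crypt organoids against FI organoids compare native adult with fetal epithelium, and also budding organoids with a mixture of spherical and budding ones in an unknown share, so that age and form go together and either may underlie the differences. Lists of mature absorption and detoxification genes shifted higher in adult organoids, and lists of spheroid and imprinted genes in fetal ones. Only part of each list was called, and no list stayed called with an estimated correlation. The matrix gene Efemp1 was at least 371-fold lower in crypt organoids (adjusted p = 0.000298), Enah at least 31.6-fold, the inhibin subunit gene Inha at least 32.1-fold, Bex4 changed by -8.98 ± 0.89 and Klhl13 by -6.90. Adgrd1 was at least 56.9-fold higher (0.000371), and Cfhr2 (7.92), the retinoid carrier gene Rbp7 (6.87 ± 0.80) and Gimap5 (6.74) rose. Alpi rose by 2.84 ± 0.48 (0.00483), while Lgr5 (-1.28 ± 0.48, 0.0962) was not called.

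Enterocyte genes rose for 14 of 45 (18 adjusted over the list alone; camera adjusted p = 7.18e-09), such as Rbp2 (3.78), the fructose transporter gene Slc2a5 (3.42) and Treh (2.96). Xenobiotic metabolism genes rose for 13 of 34 (20 adjusted over the list alone; 2.24e-09), such as Aldh1a1 (3.89), Ces1f (3.66) and Adh1 (3.25). These lists had adjusted p = 0.552 and 0.448 with an estimated correlation. Weaned-type genes rose for 5 of 12 and fell for 1 (0.00824; adjusted p = 0.471 with an estimated correlation), with Arg2 (4.50), the antibody transporter gene Pigr (2.80) and Sis (2.31), against Cyp2c55 (-1.80). Tuft cell genes rose for 3 of 18 (0.00344; adjusted p = 0.618 with an estimated correlation) and cholesterol genes for 1 of 24 (7 adjusted over the list alone; 2.81e-06; adjusted p = 0.693 with an estimated correlation). Falling lists were fetal spheroid (9 of 25, 13 adjusted over the list alone; 2.81e-06), with Msln (-5.27) and Ereg (at least 15.2-fold lower), fetal and imprinted growth (9 of 16, 10 adjusted over the list alone; 1.62e-05), with Dlk1 (-5.87) and Peg3 (at least 12.3-fold lower), and suckling-type enterocyte (6 of 13; 0.00392), with the endocytic receptor gene Cubn (-6.60) and Ass1 (-1.94). Their adjusted p = 0.471, 0.151 and 0.47 with an estimated correlation. Also falling were enteroendocrine (9 of 30; 0.000505), with Nts (-2.92) and Scg2 (-2.45), YAP targets (5 of 15, 1 rose; 0.00226), with Ccn2 (-3.86), and stem cell and Wnt targets (2 of 26; 0.023). These had adjusted p = 0.646, 0.385 and 0.701 with an estimated correlation. Prdm1, which represses adult enterocyte genes before weaning, changed by -2.76. Median, mean and test differed in sign for smooth muscle, stomach, pluripotency, antigen presentation, endothelium and neurons, with no list call.

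Of 14189 genes, limma called 1268, 442 higher and 826 lower (34.9% higher), with no overlap for 35.8% (10% by chance). The count was 717 without crypt 2, 792 without crypt 3 and 802 without FI 2. Slide as a term left 303 genes called (262 shared), and within slide 4, where crypt has 1 sample, 179 (131 shared). Efemp1 (fitted at -10.96 ± 1.45, adjusted p = 0.0142) stayed called with the term, while Alpi (2.59 ± 0.71, 0.119) did not. Of 11 lists called, 8 kept their call with the term. Cholesterol synthesis (0.422), enteroendocrine (0.459) and stem cell genes (0.172) lost it.

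iISC organoids against iFIPC organoids give the same contrast between the induced types, where organoid form goes with type in the same way. As lists, spheroid, stomach, fibroblast, YAP target and interferon genes shifted lower in iISC organoids, and tuft cell, enteroendocrine and enterocyte genes higher. Only part of each list was called, and none of these lists stayed called with an estimated correlation. The enterocyte list also lost its call with slide as a term. Gkn2 was at least 1230-fold lower (adjusted p = 0.000814), Tff1 changed by -9.94 ± 0.94 (0.000423), Pitx1 by -9.40 ± 0.93, Isx by -8.70 ± 0.77 and Mal by -7.92. The antimicrobial lectin genes Reg3a (6.72 ± 1.02) and Reg3d (at least 11.5-fold), Cfap57 (6.27), Acsm5 (at least 16.3-fold) and Dnase1 (5.28) rose most. Cdx2 (1.35 ± 0.22, adjusted p = 0.00476), Foxa2 (1.41), Gata6 (1.38) and the tuft cell kinase gene Dclk1 (1.86 ± 0.32, 0.00673) were higher, while Alpi (0.73, 0.331) and Lgr5 (0.27, 0.746) were not called.

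Fetal spheroid genes fell for 14 of 29 (16 adjusted over the list alone; camera adjusted p = 5.08e-12), with Spp1 (-7.50), Clu (-6.13) and Gja1 (at least 15.5-fold), and stomach genes for 7 of 16 (10 adjusted over the list alone; 1.6e-05), with Vsig1 (-7.83), Anxa10 (-6.63) and Ctse (-6.31). These had adjusted p = 0.174 each with an estimated correlation. Fibroblast genes fell for 8 of 17 with Pdgfrb against them at 2.31 (12 fell adjusted over the list alone; 7.45e-06), with Fn1 (at least 44.7-fold) and Col1a1 (at least 29.5-fold), and YAP targets for 6 of 17 (2.14e-05), with Ankrd1 (at least 11.1-fold). Both had adjusted p = 0.0978 with an estimated correlation. Interferon genes fell for 5 of 27 (7 adjusted over the list alone; 2.14e-05), with Zbp1 (-2.37), and Hox genes for 2 of 23 (0.0072), with Hoxc9 (at least 13.8-fold). With an estimated correlation these had adjusted p = 0.541 and 0.174. Tuft cell genes rose for 9 of 19 (10 adjusted over the list alone; 0.000158), with Rgs13 (1.85), and enteroendocrine genes for 8 of 30 (0.000357), with Sst (4.05) and Gcg (3.86). Enterocyte genes rose for 10 of 45 (14 adjusted over the list alone; 1.7e-05), with Enpep (5.14) and the glucose transporter gene Slc2a2 (3.32), and reprogramming factors for 3 of 6 (0.0236). Their adjusted p = 0.382, 0.583, 0.65 and 0.174 with an estimated correlation. Median, mean and test differed in sign for goblet cell, colon, cell cycle, cholesterol and neuron lists, with no list call.

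**Figure D4:**
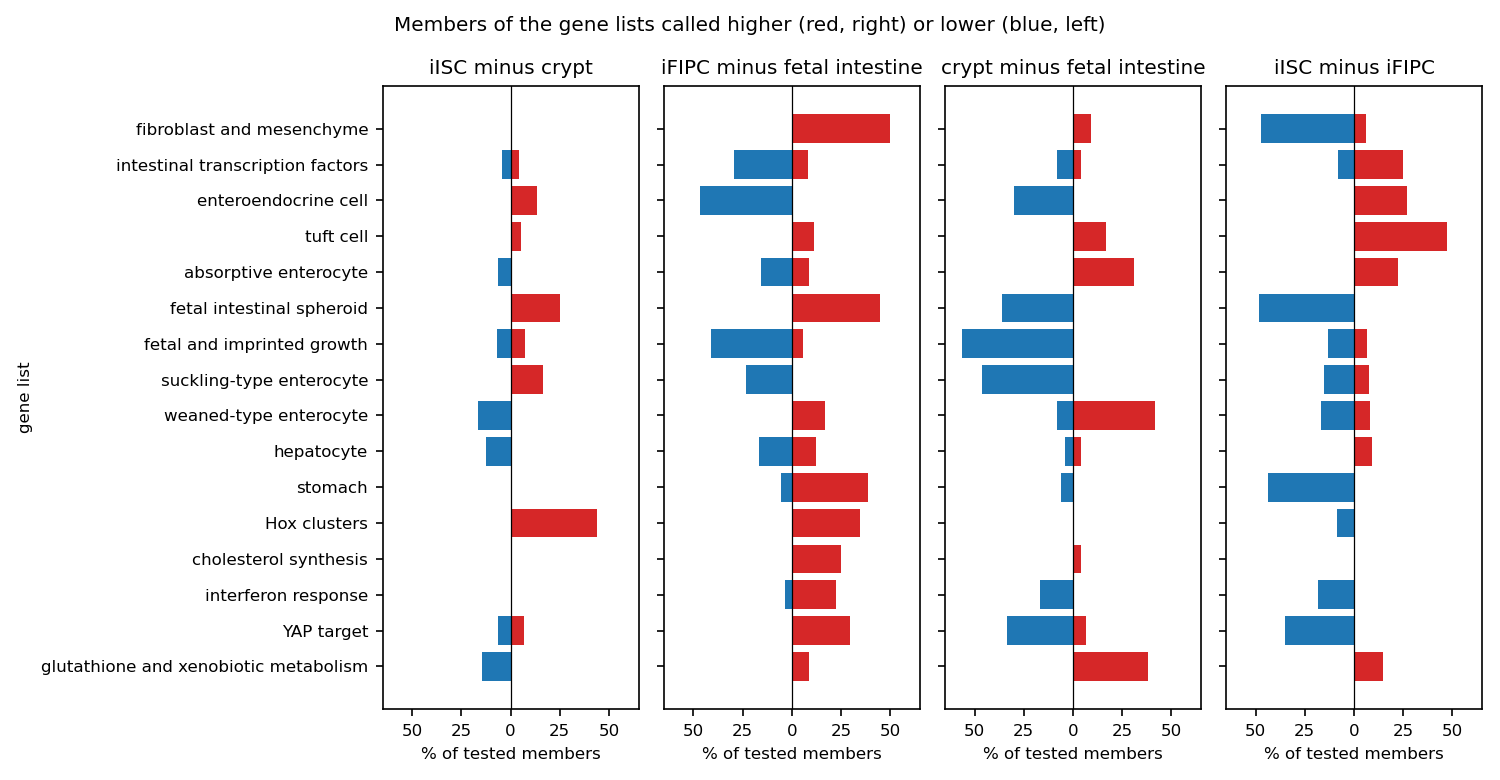
Percent of tested members of 16 gene lists called higher (red, to the right) or lower (blue, to the left) in each of 4 comparisons between organoid groups. Hox genes rose in both induced groups against their native counterparts, and fetal spheroid genes fell in both adult groups against the fetal ones.

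limma called 1076 of 13768 genes between iISC and iFIPC organoids, 441 higher and 635 lower (41% higher), and 38.3% of genes had no overlap (10% by chance). The share of higher calls was 52.1% with the stricter filter, 54.4% without a fold threshold and 30% without iFIPC 1. A slide term left 280 genes called (244 shared; 22.5% higher), and within slide 3, where iFIPC has 1 sample, 143 (102 shared; 9.8% higher). Gkn2 (fitted at -11.02 ± 1.91, adjusted p = 0.0329), Tff1 (-10.77 ± 1.36, 0.012) and Dclk1 (2.05 ± 0.18, 0.00272) stayed called with the term and Cdx2 (0.86 ± 0.22, 0.104) did not. Of the 10 lists called, 9 were called with the term, but not enterocytes (0.289).

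The adult and fetal differences of the induced and native organoids ran in parallel for part of the genes. Across 13444 genes tested in both contrasts, log2 changes correlated at r = 0.437 (rho = 0.189), across genes that are not independent replicates. Of 1135 genes called between the native groups, 848 (74.7%) had the same sign between the induced ones, against 53% of all genes. In both contrasts 124 genes were higher in the adult type (13.3 by chance) and 188 lower (25.4 by chance), and 25 went opposite ways. Fitted with slide as a term, r was 0.397. Organoid form runs with age in both contrasts, so that a shared difference may be one of form.

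**Figure D5:**
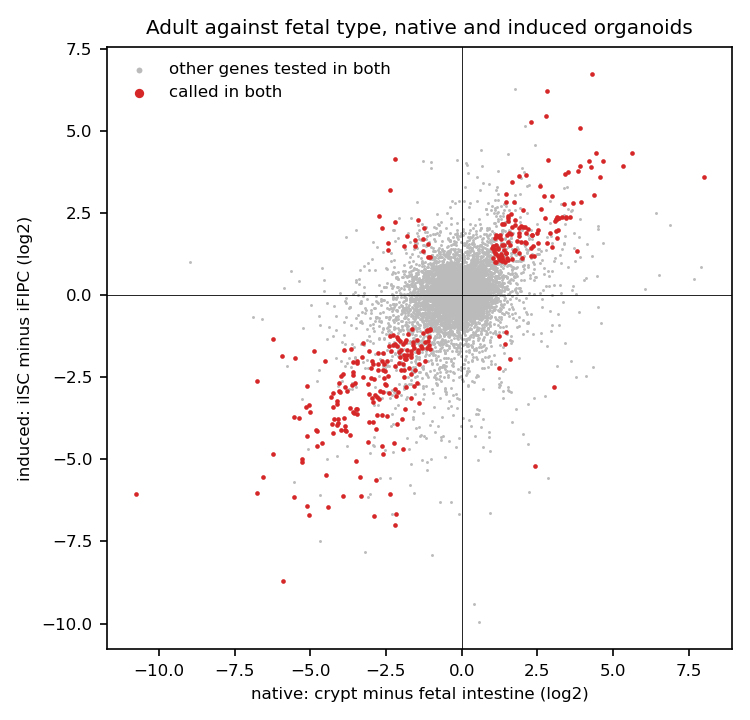
Log2 change of each gene between iISC and iFIPC organoids against that between crypt and FI organoids, with 13444 genes tested in both in grey and 337 called in both in red. Most red points lie in the quadrants where both changes have the same sign.

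The test of the difference between both contrasts (induced minus native) called 756 of 14513 genes, 468 higher and 288 lower (61.9% higher). Enteroendocrine genes differed most as a list: 8 of 30 were higher in this difference (17 adjusted over the list alone; camera adjusted p = 3.73e-07, and adjusted p = 0.415 with an estimated correlation), being lower in the adult type among native organoids and higher among induced ones. Cdx2 differed by 2.23 in the same manner. Stomach genes were lower for 5 of 18 (7 adjusted over the list alone; 0.00184; adjusted p = 0.415 with an estimated correlation). This count was 1582 without crypt 1, 319 without crypt 2, 306 without crypt 3, 443 without FI 1 and 362 without FI 2. With slide as a term 57 genes were called (46 shared; 40.4% higher), and 8 of the 9 lists called kept their call, but not cholesterol synthesis (0.345). Median, mean and test differed in sign for goblet cell, ileal bile acid, hepatocyte, YAP target, endothelium and neuron lists, with no list call.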

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

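The comparison of splits in this part was planned before the result was seen, and the tests of the stomach and fibroblast patterns were chosen after it.

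The change from fetal to adult type differed between induced and native organoids by a test of the difference itself (induced minus native, limma) for 756 genes. Genes more positive in the induced contrast were Bex4 (9.98), Emid1 (6.35), Itm2a (6.35), Klhl13 (6.23), Dlk1 (6.09), Cdx2 (2.23) and Foxa2 (1.53), and more negative ones Gkn2 (-12.57), Tff1 (-10.53), Pitx1 (-9.79), Adamdec1 (-8.23), Fstl1 (-7.63) and Gja1 (-5.01), all as fitted log2 differences, which are no bounds where a group lay at background. Lists that differed were enteroendocrine (camera adjusted p = 3.73e-07), cholesterol synthesis (0.000213), glutathione and xenobiotic metabolism (0.000213), fibroblast and mesenchyme (0.000392), stomach (0.00184), immune and blood cells (0.00184), fetal and imprinted growth (0.00392), proximal small intestine (0.0269) and reprogramming factors (0.0315). With an estimated correlation these had adjusted p = 0.219 to 0.673. Of 100 splits drawn, 2 called as many genes, the real one included. The other (2085 genes) swaps the adult and fetal labels of the native organoids alone and so adds the contrasts up, which points to structure of the samples, and the next highest called 527. Groups of 3 were too small to be searched for outlying samples.

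Stomach genes (Anxa10, Ctse, Gkn2, Muc1, Muc5ac, Tff1 and Vsig1; Ctse is also in the fetal spheroid list) were higher in iFIPC than in FI organoids. A slide effect that raised the iFIPC samples was argued against. On both slides that hold iFIPC samples, 6 of the 7 lay over 1 log2 above the other group there, iISC or crypt organoids. FI organoids share no slide with iFIPC organoids, so these values cannot decide on a slide effect that lowered the FI samples. With slide as a term the changes were larger for all but Gkn2, but so were the errors (Gkn2 11.80 ± 1.38 before and 10.39 ± 2.53 with the term), and Tff1 alone stayed called (adjusted p = 0.0416). A feature of every culture converted from fibroblasts was argued against, since 0 of the 7 were called higher by limma in iISC than in crypt organoids (4 were tested, 1 at an unadjusted p under 0.05 and in the lower direction), although 4 of the 7 rose in iHep cells. A stomach-like share of cells in these cultures may account for the pattern and stays a hypothesis, untested here, as do differences in culture that the labels do not give.

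Fibroblast genes (Cdh2, Dcn, Fn1, S100a4, Sparc, Tbx5, Twist1 and Vim) were higher in iFIPC than in FI organoids. A slide effect that raised the iFIPC samples was argued against. On both slides that hold iFIPC samples, 8 of the 8 lay over 1 log2 above the other group there, iISC or crypt organoids. For a slide effect that lowered the FI samples these values cannot decide, as FI organoids share no slide with iFIPC organoids. With slide as a term Dcn, S100a4 and Tbx5 stayed called. The others lost their call as errors grew (Fn1 6.11 ± 0.73 before, 4.81 ± 0.94 after, adjusted p = 0.0702). Remaining unchanged fibroblasts would bring all their transcripts. Of the 100 genes most abundant in MEFs and at background in crypt organoids, 69 lay far below the median change of the 8 against MEFs (-5.65). Far below means over 2 log2 and over 2 standard errors, with genes at background set to their bounds. That median cannot decide on such cells as the source of all 8, as it includes genes for which the comparison cannot decide. Taken singly, 79 of the 100 lay as far below S100a4, which fell least of the 8. This argues against such cells as the only source of that gene. For Vim the count was 60, but Vim was also expressed in crypt and FI organoids (mean levels -0.13 and -0.36, against 1.70 in iFIPC organoids). That expression limits how far Vim could fall against MEFs, so for Vim the comparison cannot decide. All 8 had been picked as higher in iFIPC organoids, and Tbx5, Twist1 and Cdh2 (77, 74 and 70 of the 100) passed the filter through that group alone. Their MEF levels (0.65, 2.15 and 0.06) lay below the lowest of the 100 (2.27). That left them little room to fall as far as most of the 100, so for them the comparison cannot decide. For Fn1, Dcn and Sparc most of the 100 did not lie that far below (48, 19 and 0 did). Such cells and expression by other cells cannot be told apart for these genes. Fibroblasts that had changed, or cells part-way through conversion, may carry the 8 genes and stay open, untested.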

How the results depend on the processing

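Averaging MEF arrays 2 and 3 was chosen after seeing the data, and the fit that keeps them separate, as first designed, became an alternative then; the others were fixed before. Counts of called genes stayed within 1.5 times under quantile normalization, the series matrix values, normexp, means over probes, no filter, a random slide effect, trended and robust moderation and all groups in 1 fit. With MEF arrays 2 and 3 separate, 4260 genes were called for iHep against MEF, 6626 for iFIPC against MEF and 7292 for iISC against MEF. The stricter filter, which tests fewer genes, gave 4611 for iISC against MEF, 243 for iISC against crypt, 652 for iISC against iFIPC and 469 for the difference of contrasts. Without a fold threshold, which lets smaller changes pass, there were 6397 for iHep against MEF, 8478 for iFIPC against iHep, 3689 for iFIPC against FI (40.6% higher), 2261 for crypt against FI and 1882 for iISC against iFIPC. Fitted alone, iISC and iFIPC gave 628. Slide as a fixed term, which leaves few samples per slide, gave 28 for iISC against crypt, 113 for iFIPC against FI, 303 for crypt against FI, 280 for iISC against iFIPC, 57 for the difference and 1641 for iHep against MEF, and single slides gave 1782 for iHep against MEF, 143 for iISC against iFIPC and 179 for crypt against FI. Without a filter, the median change of all genes was -0.22 for iFIPC against MEF and -0.15 for iFIPC against iHep.

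The correlation of the adult and fetal differences was 0.437 in the main fit. It was 0.374 with normexp, 0.342 without a filter and 0.367 with the stricter filter. Quantile normalization gave 0.417, the series matrix values and means over probes 0.418 each, and slide as a term 0.397. Gene lists called fell from 137 of 278 to 19 with an estimated correlation, the step that widens each list's spread. Leaving out each sample gave 3483 to 3957 (iHep against MEF), 6199 to 6395 (iFIPC against MEF), 6904 to 7132 (iISC against MEF), 4595 to 5162 (iFIPC against iHep), 151 to 626 (iISC against crypt), 954 to 1422 (iFIPC against FI), 717 to 1779 (crypt against FI), 745 to 993 (iISC against iFIPC), 306 to 1582 (the difference) and 0.387 to 0.461 (the correlation).

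Samples of the same number showed no clear sign of pairing: over 21 such pairs within comparisons their residuals correlated at -0.241 to 0.213, with 3 over 0.1. Residuals within groups of 2 or 3 samples are tied to each other, so these values cannot show that samples were unpaired. A replicate block in the model gave 3918, 6387, 7055, 4869, 353, 1388, 1143, 893 and 526 genes in the order of the report.

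Of 916 calls of named genes, summed over the comparisons, quantile normalization kept 899 and normexp 831. Tyrobp (-0.18) and Zfp42 (-0.09) reversed in iFIPC against iHep with normexp, and Nsdhl (-0.05), Sc5d (-0.09) and Snap25 (0.43) in iFIPC against FI with slide as a term; the cause was not tested. Slide as a term kept 145 of 476 such calls. On an array 56.14 to 68.65% of probes were well above background; changes against a group below it are bounds only.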

Other observations

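The splits of samples and the test of transcripts kept from the cells of origin were planned before their results were seen, and the other tests of this part were chosen after.

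Hox genes that rose in the induced organoids were counted by cluster, without a test between clusters. Of 11 HoxA genes present in MEFs, 5 were higher in both induced groups than in their native counterparts, against 0 of 8 HoxB, 0 of 6 HoxC and 1 of 7 HoxD genes, and against FI organoids 2 HoxC and 2 HoxD genes were higher in iFIPC organoids. Over all 13470 genes tested in both comparisons, 78 were higher in both (11 by chance), 49 lower in both (7.4 by chance) and 21 went opposite ways. These chance values take the comparisons as independent, while neither pair of groups shares a slide and 28 and 113 genes were called with slide as a term, so that the excess is not free of slide. Of the 7 stomach genes of the other part, 4 were called higher in iHep cells than in MEFs: Gkn2 (at least 7180-fold), Vsig1 (at least 26.5-fold), Tff1 (log2 change 11.83) and Anxa10 (4.73). Muc5ac (1.86), Ctse (1.51) and Muc1 (-0.92) were not called.

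Hoxa7, Hoxa9, Hoxa10, Hoxa11, Hoxa13, Hoxd9 and Tbx15 were higher in both induced groups than in their native counterparts. All were well above background in both MEF samples, and all but Hoxa13 (1 of 3) in every iHep sample. RNA of remaining fibroblasts was argued against: in iISC organoids against MEFs the fibroblast list lay -11.54 log2 from these genes (medians -11.32 and 0.22, and -10.03 apart with genes at background set to their bounds). A slide effect that raised the induced samples was argued against. On the slide with iFIPC and crypt samples, 7 of the 7 genes had both iFIPC samples over 1 log2 above both crypt samples. The iFIPC sample on the slide of the iISC samples was above the mean of the other iFIPC samples for none of them (highest difference -0.03). A slide effect that lowered the FI samples was not covered, as FI organoids share no slide with iFIPC organoids. With slide as a term Hoxa9, Hoxa11 and Tbx15 stayed called in both comparisons, and errors grew for the others. In iISC organoids Hoxa10 was 8.44 ± 0.96 before and 7.85 ± 1.51 after. In iFIPC organoids Hoxa10 shrank from 10.25 to 7.46 ± 1.51 and Hoxa7 from 4.54 to 2.57 ± 1.92. Expression kept from the cells of origin may account for this pattern, but cannot be told apart from other sources. Of the genes higher in both, 69 of 78 (88.5%) were above background in MEFs. Of those lower in both it was 27 of 49 (55.1%, two-sided Fisher's exact p = 3.59e-05). Yet the share was no higher than among all genes tested in both (90.8% of the 13469 with values on all arrays), so that the test rests on the lower genes. A posterior identity set during conversion stays open and was not tested.

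Other splits of the samples were run for each comparison of 3 against 3. For each, 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real count and the highest other were 4884 and 4 for iFIPC against iHep, 441 and 1 for iISC against crypt, 1530 and 1 for iFIPC against FI, 1268 and 145 for crypt against FI and 1076 and 0 for iISC against iFIPC. The split with 145 puts crypt 1 with FI 1 and 2 and partly follows slide 4, and the real comparison gave 303 genes with slide as a term and 179 within that slide. For the correlation of the adult and fetal differences, 1 of 100 splits drawn, the real one (0.437), was as high, and the next drawn was 0.387. Swapping the native labels turns the sign, so each split has a mirror of opposite sign that may not have been drawn. By size regardless of sign 2 of the 100 were as large, the other (-0.437) being the real groups with the native labels swapped. The next was close at -0.429, so that the margin is narrow and chance assignment of samples is not excluded.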
